A study of Mus musculus with 75 samples.

How the data were processed

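Chromatin immunoprecipitation for CTCF and Rad21 and in situ Hi-C with DpnII had been carried out on sorted G1E-ER4 cells of 5 stages between pro-metaphase and late G1, per the labels' protocols. Asynchronous cells were added for the ChIP-seq samples. Samples were grouped by assay, target and stage from their titles. CTCF ChIP-seq had 3 samples in pro-metaphase and 2 in each other group, Rad21 had 2 per group, and Hi-C had 2 per stage. Bowtie 0.12.7, SAMtools 1.7, bedtools 2.27.1 and MACS2 2.1.0 are named for the ChIP-seq samples and Bowtie2 and HiC-Pro for the Hi-C samples, with genome build mm9, per the submitters' processing notes. The tools that called domains, loops and stripes are not given in the sources used here.

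The 12 peak lists hold 1 pooled list per target and stage, with replicates merged and downsampled, per the peak names in the deposited lists. The Rad21 peak names also hold the term p1e4, and the smallest −log10 p in these lists was 4.05; it was 8.17 in the CTCF lists, whose threshold is not given in the sources used here. Each peak carries a deposited fold enrichment (a ratio) at its summit. It also carries a deposited −log10 p, a deposited −log10 q and a deposited score that equals 10 times −log10 p without its decimals. These values are the authors' own; they were used to describe, rank or filter peaks, and fold values were not compared as a change between stages.

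The 5 domain lists give start and end in bins of 10 kb, and domains may be nested. The 5 loop lists give 2 anchors, the pixel with the highest contact, an observed contact signal, an expected value and a p-value for each loop, per the file headers. The 10 stripe lists, horizontal and vertical, give the anchor, the stripe body, an observed and an expected sum and their deposited ratio as strength, per the file headers. How the authors normalized the contact values behind observed and expected is not given in the sources used here. In the horizontal lists the header named length holds the short side of the stripe, so length was taken from the coordinates of the body in all lists. The lists give no read totals, so the depth per sample is unknown, and a stage with fewer reads could have fewer features called.

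Overlaps, distances and matches were computed with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and plots were drawn with Matplotlib 3.10.9. The interval functions were tested on simulated data, 3000 and 2000 intervals, against bedtools 2.31.1 and passed 8 of 8 tests. All 20 chromosomes in the lists were used. A peak was found in another list if it shared at least 1 bp with a peak there. Domain boundaries were the distinct starts and ends of domains, matched within 20 kb. Loop size was the distance between the 2 bins of the highest pixel, and loops matched if both anchors lay within 20 kb of each other. To follow a loop's ratio across stages, the match with the highest observed/expected ratio was taken. A stripe anchor matched an overlapping anchor of a stripe of the same direction. A loop anchor or a stripe anchor carried a protein if a peak overlapped it, and a boundary did if a peak lay within 20 kb.

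The first stage of a late-G1 site, boundary or loop was the earliest stage with a match, even if a later stage had none. Co-bound sites were late-G1 Rad21 peaks that overlapped a late-G1 CTCF peak. Backgrounds came from shifting the positions around each chromosome, with both anchors of a loop moved together. The main comparisons had 100 shifts, other pairs of lists 20 and loop matching 10; Hi-C features moved in steps of 10 kb. Shares have exact 95% binomial intervals, and medians have intervals from order statistics. No p-value was computed, since pooled lists hold no replicates.

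Alternatives chosen before the data were examined were an overlap of 50% of both peaks, summits within 100 bp, a −log10 q or a fold enrichment of at least 5, and only domains in no larger domain. They also covered distances of 10 kb and 40 kb, anchors widened by 10 kb, asynchronous peaks for every stage, a loop p-value of at most 0.1 times the deposited maximum, and stripes of at least 100 kb. A −log10 q of at least 20, a peak width of at least 150 bp and lists of equal length were added after the data had been seen.

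Regions were named by a rule fixed before the data were examined: the strongest or longest features of a list under stated conditions, given by position. A rule for 8 gene lists with 125 genes had been fixed as well; the gene positions at hand belong to build GRCm38 while the lists are in mm9, so genes were not used here. Capture-C, RNA polymerase II ChIP-seq and input were not analysed here.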

Results

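Chromatin binding and chromosome folding were followed as mouse G1E-ER4 cells left mitosis and entered G1. G1E-ER4 is an immature erythroid cell line, used here uninduced. Cells were held in pro-metaphase with 200 ng/ml nocodazole for 7 to 8.5 h and released, and cells of each stage were purified by flow sorting. The stages were pro-metaphase at 0 min, ana/telophase at 25 min, early G1 at 60 min, mid G1 at 120 min and late G1 at 240 min after release. The series holds 75 samples, of which 10 are Hi-C libraries with 2 replicates in each of the 5 stages. Chromatin immunoprecipitation (ChIP-seq) was done for CTCF in 13 samples, for the cohesin subunit Rad21 in 12, and for RNA polymerase II in 14, beside 6 input samples. CTCF had 3 replicates in pro-metaphase and 2 in each other group, and Rad21 had 2 in every group; both included asynchronous cells. Capture-C, which reads contacts of chosen sites, was done in 20 samples, 12 of the parental line and 8 of a line labelled commd3_mutant. Capture-C, polymerase and input values were not analysed here.

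The values came from 12 peak lists for CTCF and Rad21, 5 domain lists, 5 loop lists and 10 stripe lists. Each list pools the replicates of its stage, so there is no spread between replicates, and none of the comparisons has a replicate test. Read depth per sample is unknown from these lists. Intervals in parentheses are exact 95% binomial intervals and cover counting error only. Peaks, loops and domains are not independent replicates, so no p-value is given across them. Positions are those of build mm9, counted from 1.

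CTCF is a DNA-binding protein that halts cohesin and marks domain and loop ends, and the CTCF lists show when its binding sites are occupied again after mitosis. Pro-metaphase held 11604 CTCF peaks, 35.0% of the 33166 in asynchronous cells. By ana/telophase the list had 33127 peaks, 99.9% of the asynchronous number, and early, mid and late G1 had 33815, 36009 and 33499. Of the asynchronous CTCF peaks, 34.6% were found in pro-metaphase (34.1 to 35.1), 86.7% in ana/telophase (86.3 to 87.1), 93.5% in early G1, 95.1% in mid G1 and 91.6% in late G1. Moving the peaks along each chromosome left at most 1.14% of them on a peak. The pro-metaphase share was 21.4% when peaks had to overlap by 50% of both. When each list was limited to its strongest 11604 peaks, the shares of the 4 later stages came to between 34.9% and 35.0%, a limit set by the length of the lists.

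The CTCF peaks present in pro-metaphase were the strong ones. Asynchronous peaks found in pro-metaphase had a median fold enrichment of 38.1 (quartiles 28.5 and 47.3), against 15.3 (10.3 and 23.6) for those not found. Among the strongest 25% of asynchronous peaks 81.9% were found (81.1 to 82.7), among the next 25% 39.3%, and among the weakest 25% 4.21% (3.79 to 4.66). In ana/telophase the strongest reached 99.9% and the weakest 61.7%. Nearly all pro-metaphase CTCF peaks were interphase sites: 99.3% overlapped an asynchronous peak and 97.3% (97.0 to 97.6) a peak in each of the 5 other lists.

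The 5 strongest pro-metaphase CTCF peaks that were present in every list had fold enrichments of 77.6 to 79.8. They lay on chromosome 17 from 12231939 to 12232543, on chromosome 11 from 116447886 to 116448709 and from 100161538 to 100162183, on chromosome 8 from 73895409 to 73895918, and on chromosome 7 from 72664354 to 72665348. The 5 strongest asynchronous CTCF peaks without a pro-metaphase peak had asynchronous fold enrichments of 58.9 to 61.7, and each was found again at all 4 later stages. They lay on chromosome 8 from 123058907 to 123059349 and from 73242027 to 73242557, on chromosome 9 from 63948266 to 63948705, on chromosome 11 from 115063348 to 115064001, and on chromosome 15 from 6859593 to 6860022.

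**Figure D1:**
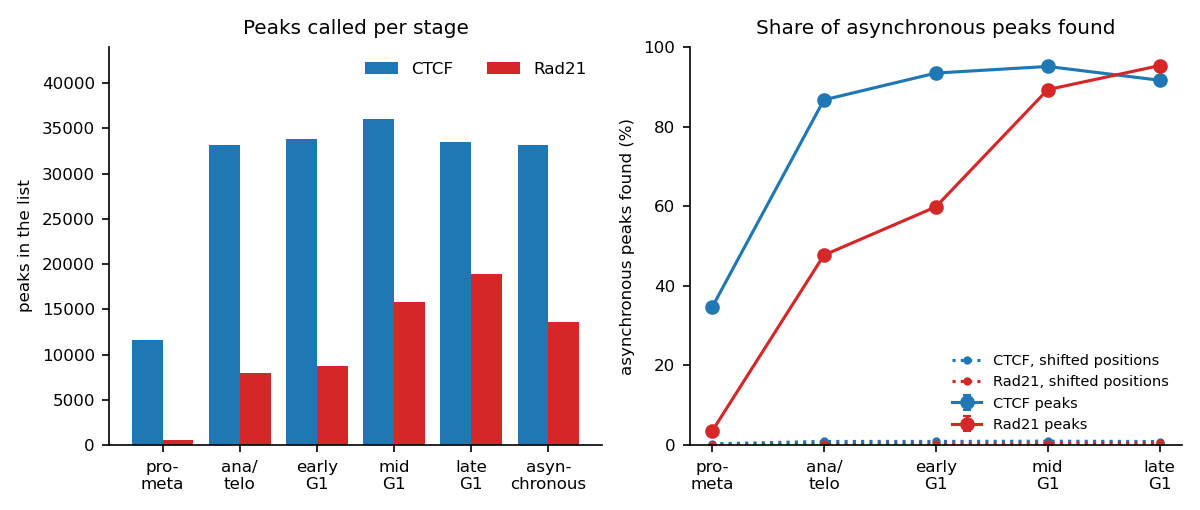
CTCF and Rad21 peaks per stage. Bars on the left give the number of peaks in each list, and points on the right give the percent of asynchronous peaks found at each stage, with exact 95% intervals that are mostly smaller than the points and with dotted lines for shifted positions. CTCF rises from 34.6% to 86.7% between pro-metaphase and ana/telophase, while Rad21 reaches 47.7% there and 89.3% in mid G1.

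Rad21 is a core subunit of cohesin, the ring complex that extrudes chromatin loops, and its lists show when cohesin returns to its interphase sites. The Rad21 lists grew through G1: 596 peaks in pro-metaphase, 7995 in ana/telophase, 8694 in early G1, 15762 in mid G1 and 18958 in late G1, against 13625 in asynchronous cells. Of the asynchronous Rad21 peaks, 3.46% were found in pro-metaphase (3.16 to 3.78), 47.7% in ana/telophase (46.9 to 48.5), 59.8% in early G1, 89.3% in mid G1 and 95.3% in late G1. Shifted peaks matched in at most 0.594% of cases. Strong sites came first here too: 86.1% of the strongest 25% of asynchronous Rad21 peaks were found in ana/telophase, against 20.1% of the weakest 25%. Late G1 held 1.39 times the asynchronous number of Rad21 peaks, and 68.4% of them were asynchronous peaks.

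The pro-metaphase Rad21 list differed in kind from the other lists. Its median peak width was 70 bp, against 202 bp to 286 bp in the other Rad21 lists, and 62.9% of its peaks had a −log10 q under 1.3. A −log10 q of at least 5 left 18 peaks, a width of at least 150 bp left 43 and a fold enrichment of at least 5 left 214. The share of asynchronous Rad21 peaks found in pro-metaphase then came to 0.139% with the q threshold and 0.316% with the width threshold, and to 0.147% with a 50% overlap of both peaks. Its strongest peak, on chromosome 8 from 108204671 to 108206367, had a fold enrichment of 16.5, was 1697 bp wide and overlapped no pro-metaphase CTCF peak. The next 4 had fold enrichments of 8.21 to 8.76 and overlapped CTCF peaks of the same stage. They lay on chromosome 3 from 101297862 to 101298065, on chromosome 1 from 182198769 to 182198939, on chromosome 15 from 11901760 to 11901842, and on chromosome 7 from 120521602 to 120521692. All 5 were Rad21 peaks in every later list.

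Cohesin sat almost entirely at CTCF sites from early G1 on. A CTCF peak of the same stage overlapped 62.4% of Rad21 peaks in pro-metaphase (58.4 to 66.3), 87.3% in ana/telophase (86.5 to 88.0), 98.5% in early G1, 96.2% in mid G1 and 95.0% in late G1. Shifted Rad21 peaks overlapped CTCF peaks in at most 1.03% of cases. Read the other way, the share of CTCF peaks with a Rad21 peak was 3.15% in pro-metaphase, 21.0% in ana/telophase, 25.3% in early G1, 42.0% in mid G1 and 53.7% in late G1. Ana/telophase held 1017 Rad21 peaks without CTCF, and 9.24% of them (7.53 to 11.2) were found in early G1, against 81.4% of the 6978 with CTCF. Many of these peaks were weak: a −log10 q of at least 5 kept 6349 ana/telophase Rad21 peaks, of which 95.8% overlapped CTCF.

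The order in which CTCF and Rad21 returned was read at the 18017 late-G1 Rad21 peaks that overlapped a late-G1 CTCF peak. CTCF had been called at 43.9% of these sites by pro-metaphase, 86.0% by ana/telophase and 95.2% by early G1. Rad21 had been called at 2.60%, 38.3% and 53.7%, and at 81.8% by mid G1. CTCF was called at an earlier stage than Rad21 at 79.2% of the sites (78.6 to 79.8), both at the same stage at 18.8%, and Rad21 earlier at 2.05%. The CTCF lists were longer than the Rad21 lists at every stage. With only as many of the strongest CTCF peaks as Rad21 peaks at each stage, 14499 co-bound sites remained; CTCF was earlier at 26.6% of them, Rad21 earlier at 34.9%, and both appeared together at 38.6%. Lists of equal length remove a lead in number by construction, whether it is real or technical, so these values do not decide the order.

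**Figure D2:**
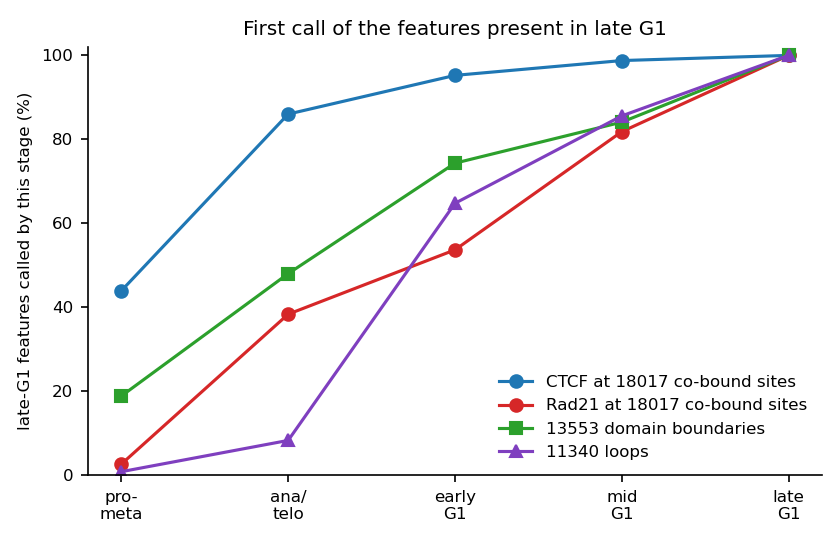
First call of features present in late G1. The lines give the percent of late-G1 features that had been called by each stage, for CTCF and Rad21 at the same 18017 sites, for 13553 domain boundaries and for 11340 loops. In ana/telophase CTCF stands at 86.0%, boundaries at 48.0%, Rad21 at 38.3% and loops at 8.25%. The lines have unlike backgrounds, so their order is not an order of events. Shifted late-G1 boundaries matched the ana/telophase list in 11.8% of cases on average, and shifted late-G1 Rad21 peaks in 0.177%.

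Domains, stretches of chromatin that contact themselves more than their surroundings, were compared across the stages to see when they reappear. The domain lists held 2509 domains in pro-metaphase, 5531 in ana/telophase, 9210 in early G1, 10286 in mid G1 and 10899 in late G1. Median size rose from 240 kb (230 to 240) in pro-metaphase to 290 kb (290 to 300) in ana/telophase, 350 kb in early G1 and 370 kb in mid and late G1. Domains over 1000 kb made up 3.47% of the list in pro-metaphase and 11.6% in late G1. Most of the growth came from nesting. Domains that lay in no larger one numbered 1943 in pro-metaphase, 3266 in ana/telophase, 3900 in early G1, 3731 in mid G1 and 3772 in late G1, and their median size went from 230 kb to 480 kb. The 3 longest domains in pro-metaphase were on chromosome 14 from 22690001 to 27060000, on chromosome 10 from 81150001 to 84870000 and on chromosome 12 from 88850001 to 92420000. In late G1 they were on chromosome 3 from 116640001 to 120820000, on chromosome 12 from 66270001 to 70220000 and on chromosome 14 from 99520001 to 103410000, and none was longer than 4180 kb.

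Domain boundaries were added in steps. Of the 13553 late-G1 boundaries, 18.8% (18.2 to 19.5) lay within 20 kb of a pro-metaphase boundary, 44.2% (43.4 to 45.0) of an ana/telophase one, 68.6% of an early-G1 one and 74.6% of a mid-G1 one. Shifted boundaries gave 6.76%, 11.8%, 17.3% and 18.6% on average, since longer lists match more often by chance. Of the 3815 pro-metaphase boundaries 52.5% (50.9 to 54.0) were present in late G1, against 19.8% after shifting.

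Late-G1 boundaries that were called early more often had CTCF and cohesin in late G1. Of late-G1 boundaries first called in pro-metaphase, 54.3% (52.4 to 56.3) had a late-G1 CTCF and a late-G1 Rad21 peak within 20 kb. The share was 52.9% for those first called in ana/telophase, 43.6% in early G1, 32.9% in mid G1 and 12.6% (11.2 to 14.1) for those called in late G1 alone. Shifted late-G1 boundaries gave 20.9% on average, so boundaries called in late G1 alone lay below that background. With the peaks of their own stage, 80 of 3815 boundaries (1.67 to 2.60%) carried both proteins in pro-metaphase, and the shares were 27.1% in ana/telophase, 26.6% in early G1, 40.3% in mid G1 and 42.4% in late G1. The shift averages were 0.655%, 9.95%, 11.4%, 18.7% and 20.9%, so the ratio to chance fell from 3.20 to 2.03. Within 10 kb the late-G1 share was 26.7%.

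**Figure D3:**
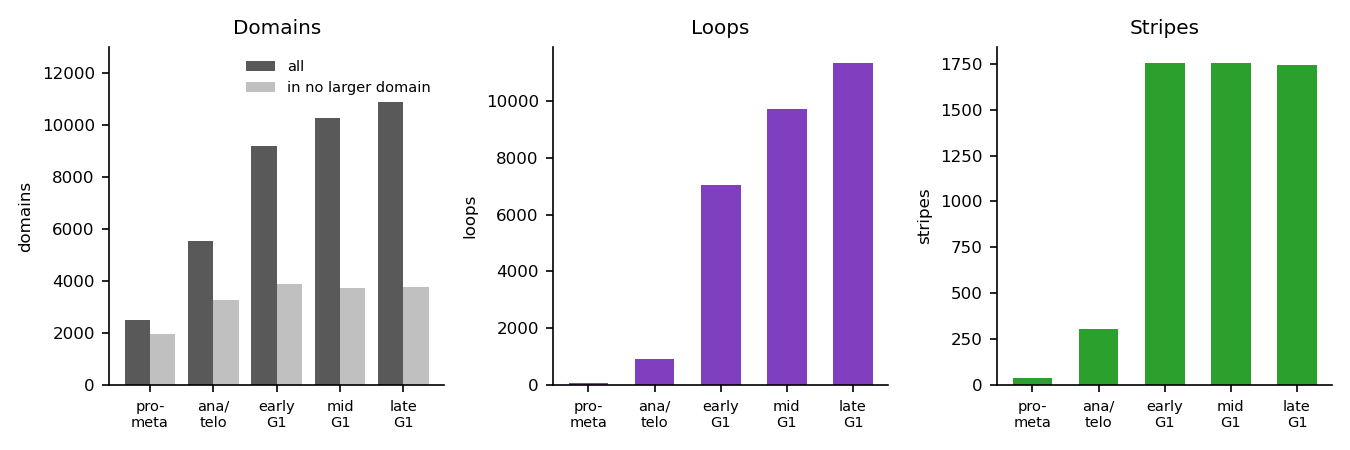
Domains, loops and stripes called per stage from Hi-C. Bars give the number of features in each list, and for domains the pale bars count domains that lie in no larger domain. Loops go from 84 to 11340, whereas stripes reach 1753 in early G1 and stay near that number.

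Loops, pairs of loci in focal contact, were compared to learn when they are called and which sizes are called first. The loop lists held 84 loops in pro-metaphase, 908 in ana/telophase, 7029 in early G1, 9714 in mid G1 and 11340 in late G1. The median distance was 100 kb (70 to 140) in pro-metaphase, 100 kb (100 to 110) in ana/telophase, 150 kb (140 to 150) in early G1 and 160 kb (160 to 170) in mid and late G1. Loops over 500 kb numbered 7, 15, 145, 479 and 571 from pro-metaphase to late G1, or 8.33%, 1.65%, 2.06%, 4.93% and 5.04% of the lists. A loop within 20 kb at both anchors had been called by ana/telophase for 8.25% (7.75 to 8.77) of late-G1 loops, by early G1 for 64.8% (63.9 to 65.6) and by mid G1 for 85.6%. Loops called before late G1 mostly stayed: late G1 held 83.5% of ana/telophase loops, 91.6% of early-G1 loops and 89.4% of mid-G1 loops, against 9.06% to 9.76% after shifting.

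By early G1 a larger share of short than of long late-G1 loops had been called. In pro-metaphase the shares did not fall steadily with size: 1.47% under 100 kb, 0.802% at 100 to 190 kb, 0.316% at 200 to 390 kb and 0.986% at 400 kb and over. Depth per stage is unknown, so later formation of long loops was not told from later detection. Called in early G1 or before were 73.1% (71.2 to 75.0) of late-G1 loops under 100 kb and 70.6% of those of 100 to 190 kb. The shares were 60.4% at 200 to 390 kb and 35.0% (32.1 to 38.0) at 400 kb and over. The step was steepest for loops with CTCF and Rad21 at both anchors, from 76.5% (73.8 to 79.1) under 100 kb to 33.4% (30.0 to 36.9) at 400 kb and over. Among the 34 loops of 400 kb and over with neither protein at any anchor, 52.9% (35.1 to 70.2) had been called by early G1. Within ana/telophase loops that were matched at every later stage and were new since pro-metaphase, 591 in number, the median observed/expected contact ratio was 3.30 in ana/telophase and 4.47, 4.75 and 4.57 in early, mid and late G1. Of several matches the one with the highest ratio was taken, and the later lists were longer. The later medians may be raised by this choice, and the expected values also differ between stages.

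With peaks of the same stage, the share of loops with CTCF and cohesin at both anchors rose from stage to stage. So did the number of Rad21 peaks, though not in equal steps. CTCF and Rad21 peaks of the same stage occupied both anchors in 0 of 84 pro-metaphase loops (0 to 4.30%), 21.9% (19.3 to 24.8) of ana/telophase loops, 32.8% of early-G1 loops, 49.6% of mid-G1 loops and 51.3% (50.4 to 52.2) of late-G1 loops. Shifted anchor pairs gave 0.768%, 1.21%, 2.80% and 3.75% in the 4 later stages, so the ratio to chance fell from 28.55 in ana/telophase to 27.2, 17.7 and 13.7. With asynchronous peaks at every stage the share was 28.9% in ana/telophase, 43.4% in early G1, 44.5% in mid G1 and 41.0% in late G1. The rise from ana/telophase to early G1 was thus also present with a fixed set of peaks, but a rise from early to late G1 was not. CTCF marked both anchors, with or without Rad21, in 50.7% of ana/telophase, 64.2% of early-G1, 67.3% of mid-G1 and 62.9% of late-G1 loops. In late G1, 10.4% of loops had no CTCF peak at either anchor.

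The pro-metaphase loops were of another kind. Of these 84 loops, 88.1% had no CTCF peak of that stage at either anchor and 97.6% no Rad21 peak, and with late-G1 CTCF peaks 11.9% (5.86 to 20.8) had one at both anchors. They were stable: 88.1% (79.2 to 94.1) were found in ana/telophase and 81.0% (70.9 to 88.7) in late G1. Late-G1 loops with neither protein at any anchor had already been called in pro-metaphase in 5.25% (3.99 to 6.76) of cases, against 0.189% (0.094 to 0.338) for loops with both proteins at both anchors.

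Among the loops with the highest observed/expected ratio and the longest loops, some were called at all 5 stages and others at 1, and most lacked CTCF at 1 or both anchors. A 2830 kb loop on chromosome 3 joined 28760001 to 28780000 with 31580001 to 31600000. It had an observed/expected ratio of 72.6 in pro-metaphase, 168 in early G1 and 141 in mid G1. In late G1 the ratio was 259, with anchors shifted by up to 10 kb, and the loop was not called in ana/telophase. Its observed value was 73.6, 74.2 and 66.6 in pro-metaphase, early G1 and mid G1, and 116 in late G1. The expected value was 1.015 in pro-metaphase and 0.442, 0.471 and 0.449 in early, mid and late G1. The higher ratios in early and mid G1 thus came from the expected value. A 3300 kb loop on chromosome 12, from 18290001 to 18310000 with 21580001 to 21600000 in pro-metaphase, had a match at all 5 stages. Ana/telophase and late G1 held neighbouring loops there. In late G1 their upstream anchors were 18250001 to 18270000 (3330 kb) and 18290001 to 18320000 (3280 kb). Matching within 20 kb may therefore have joined different loops. On chromosome 13 a 740 kb loop from 12690001 to 12710000 with 13430001 to 13460000 had a ratio of 107 in pro-metaphase and 83.7 in late G1. Its observed value was 166 in pro-metaphase and 191 in late G1, and its expected value was 1.55 and 2.28. This loop was not called in ana/telophase or early G1. Called in mid G1 alone was a 4310 kb loop on chromosome 10 between 3010001 and 3030000 and 7310001 and 7330000. A 1810 kb loop on chromosome 13, between 21840001 and 21850000 and 23640001 and 23670000, was called in early G1 alone. On chromosome 4 a loop between 113090001 and 113120000 and 113940001 and 113960000 had a ratio of 166 in ana/telophase and 99.8 in late G1 and was called at no other stage. The longest late-G1 loop, 5450 kb on chromosome 5, joined 22820001 to 22840000 with 28270001 to 28290000 and was first called in mid G1. The highest mid-G1 ratio, on chromosome 4 from 112780001 to 112800000, came from an expected value of 3.57e-16 and is no measure of strength.

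**Figure D4:**
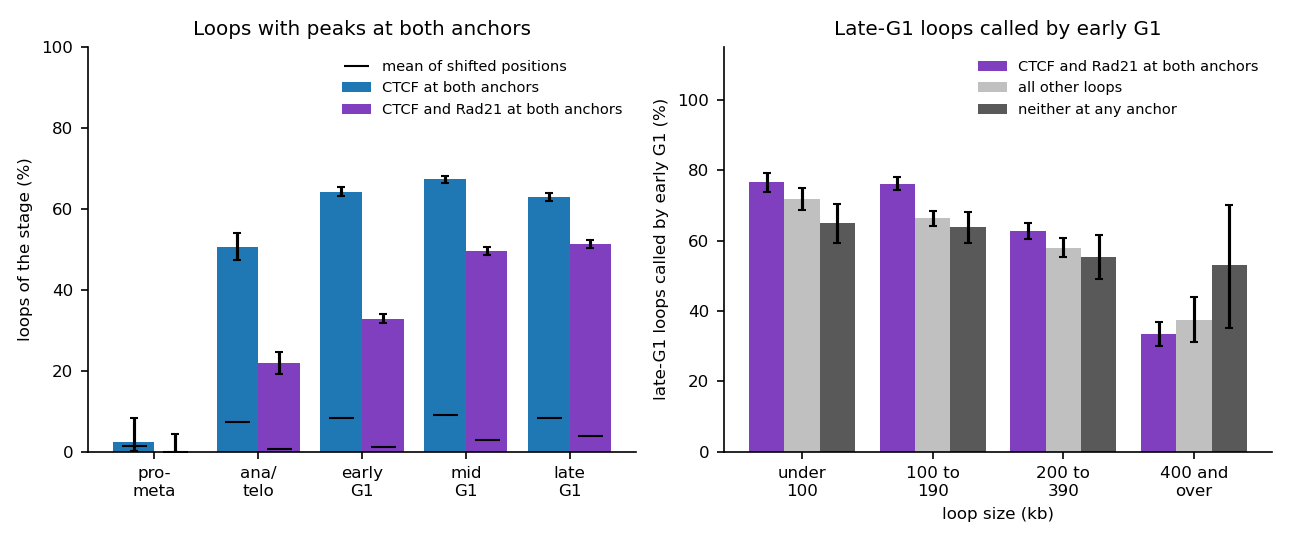
Proteins at loop anchors and time of loop calls. Bars on the left give the percent of loops of each stage with peaks of that stage at both anchors, with black marks for the mean of shifted positions, and bars on the right give the percent of late-G1 loops already called by early G1 in each size class and anchor class; error bars are exact 95% intervals. Loops with CTCF and Rad21 at both anchors fall from 76.5% under 100 kb to 33.4% at 400 kb and over.

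Stripes, in which 1 anchor contacts a continuous stretch of neighbouring chromatin, were compared to see when they form and what lies at their anchors. The lists held 39 stripes in pro-metaphase, 307 in ana/telophase, 1753 in early G1, 1754 in mid G1 and 1745 in late G1, with close to equal numbers of horizontal and vertical stripes at each stage. The stripe lists thus had their late-G1 length by early G1, when loops stood at 62.0% of theirs. Horizontal and vertical stripes numbered 878 and 875 in early G1, 876 and 878 in mid G1, and 873 and 872 in late G1. The stripe caller and its cutoffs are not given in the sources used here. A length set by the caller was therefore not told from stripes being complete by early G1. Early-G1 stripe anchors overlapped late-G1 anchors of the same direction in 93.0% of cases (91.7 to 94.2), against 1.19% after shifting. The median body length was 270 kb (190 to 320) in pro-metaphase, 220 kb (200 to 230) in ana/telophase, 270 kb (260 to 280) in early G1, 320 kb (310 to 330) in mid G1 and 310 kb (300 to 320) in late G1. Of the 850 stripes whose anchor started at the same position in early, mid and late G1, 61.6% were longer in mid G1 than in early G1 and 31.2% were shorter.

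From early G1 on, most stripe anchors carried CTCF and cohesin. Both proteins, from the peaks of the same stage, were at 41.0% (35.5 to 46.8) of ana/telophase stripe anchors, 72.4% (70.2 to 74.5) in early G1, 83.1% in mid G1 and 84.2% (82.4 to 85.9) in late G1, against 3.75%, 6.22%, 11.7% and 13.4% after shifting. With anchors widened by 10 kb on each side the ana/telophase share was 64.8%. In pro-metaphase 0 of 39 anchors had both (0 to 9.03%), and 23.1% did when asynchronous peaks were used. The longest ana/telophase stripes extended from 1 place on chromosome 11, an 860 kb horizontal stripe from an anchor at 116600001 to 116620000 and an 840 kb vertical stripe from 116610001 to 116620000. The next longest were a 750 kb horizontal stripe on chromosome 3 from 94240001 to 94260000 and a 640 kb vertical stripe on chromosome 1 from 183760001 to 183780000. In late G1 the longest horizontal stripes were 2040 kb on chromosome 14 from 97340001 to 97370000 and 1630 kb on chromosome 15 from 61790001 to 61830000. The longest vertical ones were 1450 kb on chromosome 1 from 132240001 to 132270000 and 1390 kb on chromosome 13 from 83790001 to 83810000.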

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

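A −log10 q of at least 20, a peak width of at least 150 bp and both kinds of equal-length lists were chosen only after the results had been seen; all other alternatives were written down before the data were examined. Of 168 values of the main results under an alternative, 77 stayed within their interval or within 1.5 times the count, 90 moved and 1 reversed. Under every alternative tried, the shares of asynchronous Rad21 peaks and late-G1 boundaries found still rose from stage to stage. The reversal concerned the order of CTCF and Rad21 at co-bound sites. With as many CTCF as Rad21 peaks at each stage, CTCF was earlier at 26.6% of sites in place of 79.2%, and the difference between CTCF earlier and Rad21 earlier went from 77.1 to −8.31 percentage points. Equal lists leave CTCF no lead in number by construction, so this reversal does not weigh against a true lead. Equal-length CTCF lists also gave 35.0%, 34.9%, 35.0% and 34.9% of asynchronous CTCF peaks in ana/telophase, early, mid and late G1, because 11604 peaks cannot cover more. For all other values below the cause was not tested. An overlap of 50% of both peaks gave CTCF shares of 21.4%, 84.9%, 92.2%, 94.2% and 89.996% from pro-metaphase to late G1, and Rad21 shares of 0.147%, 44.3%, 58.6%, 88.6% and 93.3%. A −log10 q of at least 20 gave CTCF shares of 30.6% in pro-metaphase, 85.8% in ana/telophase, 94.8% in mid G1 and 89.5% in late G1. Summits within 100 bp gave CTCF shares of 86.2% in ana/telophase, 93.2% in early G1 and 94.8% in mid G1, and a Rad21 share of 94.7% in late G1. Rad21 peaks with a CTCF summit made up 86.2%, 97.7%, 95.3% and 94.2% from ana/telophase to late G1 and 95.1% in asynchronous cells. A −log10 q of at least 5 left 18 Rad21 peaks in pro-metaphase and gave Rad21 shares of 0.139% in pro-metaphase, 43.9% in ana/telophase, 90.2% in mid G1 and 95.9% in late G1. Rad21 peaks with CTCF then made up 88.9%, 95.8%, 99.1%, 97.1% and 96.0% from pro-metaphase to late G1 and 97.0% in asynchronous cells. At co-bound sites CTCF was then earlier at 83.3%, the difference was 82.1 points, and Rad21 had been called by ana/telophase at 34.25%. A fold enrichment of at least 5 left 214 pro-metaphase Rad21 peaks. A width of at least 150 bp left 43, with Rad21 shares of 0.316% in pro-metaphase and 45.4% in ana/telophase, and with CTCF at 90.7% and 90.3% of Rad21 peaks. Boundaries within 10 kb gave 13.9%, 35.6%, 59.0% and 65.5% of late-G1 boundaries from pro-metaphase to mid G1, and within 40 kb 25.05%, 53.1%, 76.8% and 81.9%. Peaks within 10 kb of the boundary gave 1.10%, 16.3%, 15.6%, 25.1% and 26.7% with both proteins from pro-metaphase to late G1. Domains in no larger domain numbered 3266, 3900, 3731 and 3772 from ana/telophase to late G1, since nested ones were left out, and their medians were 390 kb, 470 kb and 480 kb in early, mid and late G1. With asynchronous peaks, both proteins lay at both anchors of 28.9%, 43.4%, 44.5% and 41.0% of loops from ana/telophase to late G1. For stripe anchors these peaks gave 23.1% in pro-metaphase, 51.5% in ana/telophase, 77.6% in early G1 and 81.4% in late G1. Anchors widened by 10 kb gave 31.3%, 38.7%, 57.5% and 59.9% of loops and 64.8%, 84.9%, 93.0% and 93.9% of stripe anchors from ana/telophase to late G1. Loop anchors within 10 kb gave 6.91%, 59.3% and 81.7% of late-G1 loops called by ana/telophase, early and mid G1, and within 40 kb 10.8%, 72.1% and 90%. A loop p-value of at most 0.0009023 kept every loop count within 1.5 times. A −log10 q of at least 5 removed no CTCF peak and a stripe length of at least 100 kb removed no stripe, so both tested nothing there. No paired analysis was possible because the lists are merged per stage and carry no replicate numbers, and leaving out each replicate in turn was not run for the same reason. Depth is unknown, and it limits how far counts of features can be compared between stages.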

Other observations

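Of the tests below, the noise and fragment-setting tests of Rad21, the carry-over test of the pro-metaphase loops and the test with matched strength were written after the values they measure had been seen. The others were written before their values were computed, though the peak tables had prompted the idea of testing strength at co-bound sites.

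Some loops of earlier stages were not called in late G1. The late-G1 list lacked 150 of the ana/telophase loops (16.5%), 591 of the early-G1 loops (8.41%) and 1027 of the mid-G1 loops (10.6%). The early-G1 loops without a late-G1 match had CTCF and Rad21 at both anchors in 18.8% of cases (15.7 to 22.2), against 34.1% (32.9 to 35.3) for those with a match, and their median observed/expected ratio was 2.73 against 3.45. Loss of a loop was not told from a weak loop missed at the threshold or in matching. For mid-G1 loops the shares were 36.3% (33.4 to 39.3) and 51.2% (50.1 to 52.2). For ana/telophase loops they were 19.3% (13.3 to 26.6) and 22.4% (19.5 to 25.6). Of the pro-metaphase loops 58 were matched at every later stage, with a median observed/expected ratio of 6.06 in pro-metaphase, 8.72 in ana/telophase, 9.21 in early G1, 8.31 in mid G1 and 6.97 in late G1.

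The ana/telophase Rad21 peaks without CTCF had a median fold enrichment of 4.25, against 6.27 for those with CTCF. Of the 1017 peaks, 14.8% (12.7 to 17.2) were found in mid G1, 15.4% (13.3 to 17.8) in late G1 and 13.9% (11.8 to 16.1) in asynchronous cells. The 6978 with CTCF were found in 94.4%, 96.7% and 91.2% of cases.

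The first pattern weighed was the short list of narrow Rad21 peaks in pro-metaphase. Random noise was excluded as the whole cause: of the 375 peaks with a −log10 q under 1.3, 75.7% (71.1 to 80.0) overlapped an asynchronous Rad21 peak, against at most 1.07% after shifting. Interphase cells carried over in the sort could account for the sites, since those found sat at a median percentile of 92.6 (quartiles 79.6 and 97.9) by fold enrichment among asynchronous peaks. The smallest width was 50 bp against 149 bp in any other list, which a shorter fragment setting of the peak caller may explain. Retention of some cohesin in pro-metaphase stays open beside carried-over cells, and no biological explanation was tested.

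The second pattern was the set of 84 pro-metaphase loops, most of them without CTCF. If carried-over interphase cells brought all late-G1 loops alike, these loops would have the CTCF share of late-G1 loops. They did not: 11.9% (5.86 to 20.8) of these loops had late-G1 CTCF peaks at both anchors, against 62.9% of late-G1 loops. A small carry-over might bring strong loops only, and their CTCF share was not computed. Late-G1 loops already called in pro-metaphase had a median late-G1 observed/expected ratio of 5.84, against 3.28 for all late-G1 loops. The test therefore does not exclude carry-over of strong loops. Contacts fixed by the DNA itself, such as differences between the genome of these cells and the reference assembly, might give equal contact at all stages, and the median ratio of late-G1 to pro-metaphase observed/expected was 1.12 (0.95 to 1.23) over 68 matched loops. The median ratio over the 58 loops matched at every stage was not level in between, with 6.06 in pro-metaphase and 9.21 in early G1. The expected values behind it also differ between stages, and taking the match with the highest ratio may raise the later values. Contact brought by a small share of carried-over cells would be far weaker in pro-metaphase than in late G1. The median ratio of 1.12 (0.95 to 1.23) argues against this for the 68 matched loops. Only loops strong enough to be called in pro-metaphase entered that ratio, so carry-over is not excluded. Fixed contacts stay open, and no biological explanation was tested.

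The third pattern was the lead of CTCF over Rad21, where the biological explanation is a true difference between stages and the technical one is weaker Rad21 enrichment that passes the threshold later. At the 768 co-bound sites (4.26%) where the late-G1 Rad21 −log10 p was at least that of CTCF, CTCF was earlier at 29.8% (26.6 to 33.2) and Rad21 at 16.7% (14.1 to 19.5), yet by ana/telophase CTCF had been called at 52.7% (49.1 to 56.3) and Rad21 at 49.0% (45.4 to 52.6). These sites were picked for strong Rad21 in late G1 alone, which by itself favours a late first call of Rad21, so the bound set beforehand was wrong and excludes nothing. Across asynchronous peaks matched by fold enrichment, CTCF led by 3.66 percentage points in pro-metaphase, 13.0 in ana/telophase (39.0 unmatched) and 13.3 in early G1 (4.41, 11.1 and 6.75 when matched by −log10 p), and the difference was −9.30 in mid G1 and −26.0 in late G1. A lead at equal asynchronous strength, up to early G1, argues against weaker enrichment as the whole cause. The bounds of the lists were unlike, however: the smallest −log10 p was 8.17 for CTCF and 4.05 for Rad21. Matched CTCF peaks thus faced the higher bound, which may lower their shares and bear on the negative differences. The matched CTCF share itself went from 81.1% in mid G1 to 70.0% in late G1, nearly as large a step as the lead. Without replicates, a difference between lists was not told from one between stages. Weaker enrichment and a true difference between stages both stay open.

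A uniform weakening of all CTCF peaks was tested as an account of the CTCF peaks kept in pro-metaphase. In pro-metaphase 94.5% (93.7 to 95.3) of the strongest 10% of asynchronous CTCF peaks were found. Equally long lists held 96.4% (95.7 to 97.0) in ana/telophase, 99.3% in early G1, 99.2% in mid G1 and 98.9% in late G1. The pro-metaphase share was thus the lowest, by a few points. Each list held 11604 peaks, far more than the 3317 looked up, so every share lay near its ceiling and the test could hardly fail. Neither a uniform weakening nor interphase cells carried over is excluded by this value, and it does not separate them. Retention of CTCF at certain sites was not tested and stays open as well.

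Another hypothesis was that loops are called earlier where Rad21 already marks both anchors in ana/telophase. Among the 5816 late-G1 loops with both proteins at both anchors, 43.9% of those called by early G1 had such Rad21 peaks, against 28.7% of those called later. The difference was at least 10.2 percentage points in each of 4 equal groups by late-G1 observed/expected, which is consistent with the hypothesis at the limit of 10 points set beforehand; an effect of loop size was not removed.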
